A study of Homo sapiens with 12 samples.

How the data were processed

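The series holds RNA sequencing of 12 samples, 3 each of MCF-7 and MDA-MB-231 cells treated with DMSO or DATS. Samples were assigned to groups and numbered by the sample titles and treatment labels. Per the labels' protocols, cells were harvested with trypsin, total RNA was extracted with the RNeasy mini kit, and libraries were made by a standard Illumina procedure, and the samples were prepared 3 times independently. The submitters' processing notes name STAR 2.6.1d, DESeq2 and the GRCh38/hg38 genome. The counting tool, its strand setting and the annotation release are not given in the sources used here.

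The authors deposited a table of FPKM for 58735 genes in each sample, and for each line a table of genes with an unadjusted p-value of 0.05 or less. Those comparison tables hold raw read counts of the listed genes, the authors' log2 fold changes of DATS over DMSO, and unadjusted and adjusted p-values. All 58735 gene identifiers are in GENCODE release 29 (Ensembl release 94), and the deposited lengths of all 2013 listed genes with a length equal the union of exons there. The authors' deposited FPKM divides each read count by gene length and by a normalized library size rather than by the sum of reads. This scales every gene of a library alike and leaves fold differences dependent on the authors' size factors. The tables also hold 24 columns of per-sample values that were not used. In the authors' table for MDA-MB-231, 928 genes carry an adjusted p of exactly 1. Of 792 such genes that were tested here, DESeq2 gave 774 no adjusted p because of its filter on mean count. Among the genes listed for MDA-MB-231, 28 without an adjusted p under 0.05 have a smaller unadjusted p than 0.0005, the largest among the genes with one.

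Read counts were recovered from the deposited FPKM by multiplying with gene length and library size. All of the 265937 values above 0 (100.0%) came out whole within 0.01 reads, and all 12078 recovered values that could be compared equal the deposited counts. Reads per library numbered 15339115 to 18700296, so a count of 5 reads carries a large counting error. The recovered reads served for depth and for the alternative tests with edgeR and DESeq2. Pairs of libraries of one group differed by more than counting noise, with a chi-square per degree of freedom from 7.43 to 45.84, so no library was counted as a duplicate. Mitochondrially encoded genes held 9.19 ± 0.42% of reads in MCF-7 DMSO, 8.45 ± 0.61% in MCF-7 DATS, 7.19 ± 0.29% in MDA-MB-231 DMSO and 6.74 ± 1.52% in MDA-MB-231 DATS (SD, n = 3).

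Before the data were examined, the tests, samples, gene lists, rule for named genes and other settings to try were fixed. The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided) on log2(FPKM + 1), with Benjamini-Hochberg adjustment and a threshold of 0.05. Each line was fitted alone, on genes with at least 1 FPKM in at least 3 of the fitted libraries. The comparison of the 2 responses used all 12 libraries and genes passing the filter in both lines, and the baseline comparison used the 6 DMSO libraries. The 25 gene lists were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over 50 tests (25 lists in 2 lines), and again with an estimated correlation. They cover NRF2 targets, the integrated stress, unfolded protein, heat shock, interferon and NF-kB responses, metallothioneins, p53, FOXO and estrogen receptor targets, G2/M and G1/S genes, BCL2 and IAP families, cholesterol and fatty acid synthesis, glycolysis, sulfur and glutathione metabolism, mesenchymal, luminal and stem-like markers, immediate-early, hypoxia, tubulin, proteasome and mitochondrially encoded genes. Named genes are the 10 largest increases and decreases among called genes of each DATS comparison with at least 5 FPKM in the higher group and no overlap of the groups' libraries (none were called), the 5 largest in each direction of the difference between the lines with at least 5 FPKM in any group (none qualified), the 5 largest in each direction between the lines with at least 5 FPKM in the higher one, the luminal and mesenchymal lists, and, per comparison, up to 4 members of each list with the smallest p. Genes named from the authors' deposited tables, the RPS3AP5 call (under 5 FPKM in all groups), its parent gene RPS3A EVL and the genes behind small counts under other settings were chosen after their values were seen.

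The scripts were tested on simulated reads with known changes. In a simulated MCF-7 comparison of 11701 genes, limma recovered 60.2% of genes changed 2-fold and 97.9% of genes changed 4-fold, with 5 false calls. For MDA-MB-231 (11317 genes) it recovered 93.9% and 100% with 9 false calls, and for the difference between the lines (9893 genes) 50% and 98% with 14 false calls. Camera found all 100 shifted lists in each simulated line and called 3 and 2 of 100 unshifted lists, at an unadjusted p under 0.05. The lists were random and the shift was 0.5 on the log2 scale. Genes were drawn independently, without the correlation between members of real lists, estimated at 0.9 for G1/S genes in MCF-7. The simulation therefore does not measure the rate of false calls among the real lists, or the power for smaller shifts. For the difference between the lines, both simulated lines shared a baseline mean per gene, and their libraries were drawn independently. The recovery and false calls given for that difference therefore need not hold for the real lines.

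The settings fixed in this way were pseudocounts of 0.1 and 0.5, no filter or a filter at 5 FPKM, median-of-ratios, TPM and quantile scaling, eBayes without a trend or with robust estimation, the replicate number as a block, leaving out each library in turn, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, all 12 libraries in one fit, and a 2-fold minimum. Added after the data were seen were a correction that takes out of each library its smooth trend with GC content and gene length (natural splines with 4 degrees of freedom each), leaving out both libraries numbered 2, protein-coding genes alone, TPM and quantile scaling for the lists, treatment and number as a block across the lines for the difference between them, and the lists tested on that difference. GC content was computed over all GENCODE transcript sequences of a gene together, and 2 tested genes in each line without a value were given the median. Figures were drawn from the result tables, and Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 read the files.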

Results

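Gene expression was measured by RNA sequencing in MCF-7 and MDA-MB-231 human breast cancer cells treated with diallyl trisulfide (DATS), an organosulfur compound derived from garlic. MCF-7 is an estrogen receptor-positive line of the luminal subtype and MDA-MB-231 is an estrogen receptor-negative line of the basal subtype. Cells received 20 µM DATS or the vehicle DMSO at 0.07% for 16 h. Each of the 4 groups held 3 libraries, prepared independently per the labels, which gave 12 libraries in all. Reads assigned to genes ranged from 15339115 to 18700296 per library, and between 11335 and 11860 genes per library reached 1 FPKM, the deposited unit of expression scaled for gene length and library size. All fold differences below are on the log2(FPKM + 1) scale, which understates the change of genes with low values.

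The DMSO-treated cells were compared first, to describe the baseline of the 2 subtypes. MCF-7 cells expressed the epithelial luminal genes and MDA-MB-231 cells most of the mesenchymal genes. All 18 luminal genes tested were lower in MDA-MB-231, and 12 of 14 mesenchymal genes were higher, while SNAI1 and TGFBI did not pass the test (limma adjusted p = 0.981 and 0.193). Adjusted over the list alone, the counts were the same, 18 and 12. E-cadherin (CDH1), the epithelial adhesion molecule, stood at 126 ± 3.33 FPKM (SD, n = 3) in MCF-7 and at 0.0379 ± 0.0211 in MDA-MB-231. The luminal transcription factors GATA3 and FOXA1 had means of 199 ± 32.9 and 111 ± 9.18 FPKM in MCF-7 against 3.54 ± 0.502 and 0.0136 ± 0.0138 in MDA-MB-231. Keratin 8 (KRT8) was lower in MDA-MB-231 by a log2 difference of -4.2 ± 0.07 (SE), from 1340 ± 45.7 to 71.9 ± 1.89 FPKM. Vimentin (VIM), the intermediate filament of mesenchymal cells, was at 0.128 ± 0.063 FPKM in MCF-7 and at 210 ± 25 FPKM in MDA-MB-231. ZEB1, a repressor of epithelial genes, was at 0.0171 ± 0.0161 and 7.63 ± 0.806 FPKM in the same order.

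Among all genes with at least 5 FPKM in the higher line, the 5 largest log2 differences toward MDA-MB-231 belonged to SERPINE1, G0S2, SAA1, GPX1 and AXL. SERPINE1, which encodes the plasminogen activator inhibitor PAI-1, was at 0.678 ± 0.634 FPKM in MCF-7 and 574 ± 56.7 in MDA-MB-231 (SD, n = 3), and the receptor tyrosine kinase AXL was at 0.0534 ± 0.0369 and 220 ± 15.9. Toward MCF-7 the 5 largest belonged to TFF1, DSCAM-AS1, SPTSSB, CD24 and S100A14. The estrogen-induced secreted protein TFF1 had 2260 ± 294 FPKM in MCF-7 and 0.583 ± 0.188 in MDA-MB-231, and SPTSSB had 227 ± 38.5 FPKM in MCF-7 and was listed at 0 in all MDA-MB-231 DMSO libraries. In total, limma called 9619 of 12628 genes tested at an adjusted p under 0.05, of which 4954 were higher and 4665 lower in MDA-MB-231. EdgeR called 9586 and DESeq2 9480 of the same genes tested.

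**Figure D1:**
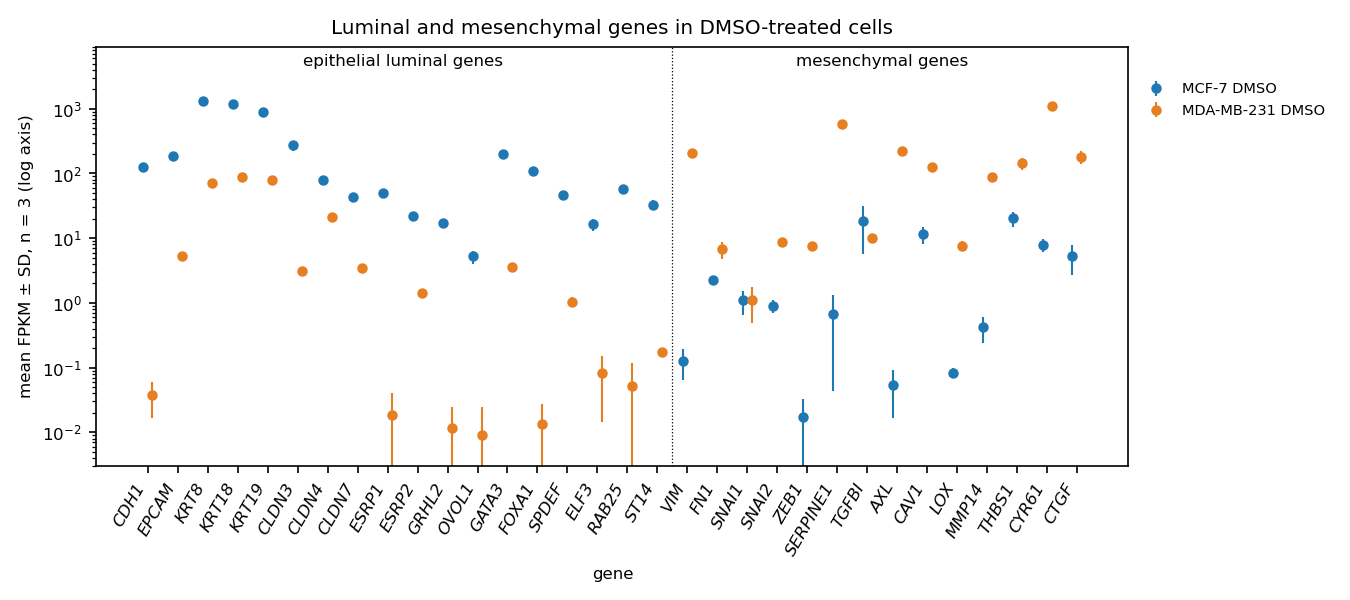
Mean FPKM of the luminal and mesenchymal genes in DMSO-treated MCF-7 (blue) and MDA-MB-231 (orange) cells, on a log axis, with bars for the SD over 3 libraries (bars that reach the lower edge extend beyond it). All 18 luminal genes sit higher in MCF-7. Of the mesenchymal genes, TGFBI sits lower in MDA-MB-231 and SNAI1 is at nearly the same level in both lines, and the other 12 sit higher in MDA-MB-231.

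The effect of DATS in MCF-7 cells was examined through gene lists and through single genes. As a group, estrogen receptor targets were lower and the NF-kB inflammatory genes that could be tested were higher in DATS-treated MCF-7 cells. Of 18 estrogen receptor targets, 16 had a lower mean, with a mean log2 difference of -0.39 ± 0.26 (SD over the members; camera adjusted p = 3.82e-07, and adjusted p = 0.71 with an estimated correlation). Among the 4 members with the smallest p, PGR, the progesterone receptor, stood at 1.88 ± 0.779 FPKM in DMSO and 0.844 ± 0.322 in DATS (SD, n = 3), the scaffold protein gene PDZK1 at 4.47 ± 1.82 and 1.85 ± 0.708, the receptor tyrosine kinase RET at 8.05 ± 2.64 and 4.25 ± 1.7, and the transcription factor MYB at 4.98 ± 1.87 and 2.52 ± 0.564. TFF1, also in the list, stood at 2260 ± 294 FPKM in DMSO and 2300 ± 301 in DATS. Of 18 members of the NF-kB list, 8 passed the expression filter in MCF-7, and the cytokine genes IL6, CXCL8 and IL1B were among those that did not. All 8 NF-kB genes tested had a higher mean in DATS, with a mean log2 difference of 0.52 ± 0.25 (camera adjusted p = 9.75e-06, and adjusted p = 0.71 with an estimated correlation). TNFAIP2 stood at 6.72 ± 0.464 FPKM in DMSO and 16 ± 7.85 in DATS, the NF-kB subunit RELB at 5.43 ± 1.1 and 9.54 ± 2.84, and TNFAIP3, which encodes the NF-kB inhibitor A20, at 2.88 ± 1.17 and 4.76 ± 0.215. These 3 passed when adjusted over the list alone (limma adjusted p = 0.0453 for each) and not over all genes (adjusted p = 0.841). The fourth named member, the NF-kB subunit NFKB2, stood at 17.8 ± 2.97 and 23.4 ± 2.38 FPKM. The estrogen receptor target list mean, relative to all 6 MCF-7 libraries, was 0.34, -0.06 and 0.31 in DMSO 1, 2 and 3 and -0.15, -0.04 and -0.4 in DATS 1, 2 and 3, so that DMSO 2 lay at the level of DATS 2. The NF-kB list mean of DMSO 2 (0.05) lay next to that of DATS 1 (0.06). At the preset correlation, both list calls stayed past the threshold without any single library, at adjusted p values up to 0.00324 for the estrogen receptor targets and 0.0026 for the NF-kB genes.

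Stress and cell cycle lists also passed the list test in MCF-7 cells. NRF2 targets, the antioxidant and detoxification genes, had a mean log2 difference of 0.28 ± 0.25 with 20 of 22 members higher (camera adjusted p = 0.000883, and adjusted p = 0.773 with an estimated correlation). AKR1B10, an aldo-keto reductase, stood at 2.65 ± 0.646 FPKM in DMSO and 5.92 ± 2.61 in DATS (SD, n = 3), sulfiredoxin (SRXN1) at 1.06 ± 0.444 and 2.17 ± 1.05, ABCC3 at 18.6 ± 4.59 and 25.4 ± 3.11, and OSGIN1 at 5.42 ± 1.08 and 7.4 ± 1.69. Of 18 p53 targets, 17 had a higher mean, with a mean log2 difference of 0.29 ± 0.22 (camera adjusted p = 0.00418, and adjusted p = 0.773 with an estimated correlation). BTG2 stood at 18.2 ± 7.29 and 28.2 ± 10.5 FPKM, BBC3, which encodes the proapoptotic protein PUMA, at 5.14 ± 2.85 and 8.23 ± 4.16, BAX at 29.5 ± 5.22 and 38.4 ± 9.51, and TP53INP1 at 15.9 ± 4.35 and 21.1 ± 5.27. Of 18 G1/S and replication genes, 17 had a lower mean, with a mean log2 difference of -0.31 ± 0.16 (camera adjusted p = 0.00166, and adjusted p = 0.773 with an estimated correlation). PCNA, the replication clamp, stood at 112 ± 40.6 FPKM in DMSO and 77.6 ± 28.4 in DATS, thymidylate synthase (TYMS) at 10.3 ± 2.19 and 7.89 ± 0.928, RRM2 at 20.7 ± 6.73 and 14.7 ± 4.71, and CDCA7 at 5.42 ± 2.06 and 3.61 ± 1.83. In the p53 list and in the G1/S list, 0 members had an unadjusted p under 0.05 in limma. In both lists, 0 members had all DATS libraries on one side of all DMSO libraries. In the NRF2, p53 and G1/S lists the libraries numbered 2 stood apart from their groups. The NRF2 list mean, relative to all 6 MCF-7 libraries, was 0.18 in DMSO 2 and -0.16 in DATS 2, the p53 list mean was 0.24 and -0.21, and the G1/S list mean was -0.36 and 0.34. Without DATS 1 the calls of the NRF2, p53 and G1/S lists were lost (adjusted p = 0.171, 0.329 and 0.451), and without DMSO 1 so were those of the p53 and G1/S lists (adjusted p = 0.0682 for both). Without DATS 2 the camera adjusted p of the 3 lists fell to 1.39e-08, 8.74e-08 and 4.14e-10 in the same order. Without both libraries numbered 2, tried after the data were seen, it was 1.04e-09, 1.71e-09 and 3.81e-17. These values used the preset correlation, and the calls depended on which libraries were included.

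Proteasome subunits were higher as a group in MCF-7, with a higher mean in 26 of 30 members (mean log2 difference 0.11 ± 0.14, camera adjusted p = 0.0293, and adjusted p = 0.774 with an estimated correlation), as were cholesterol synthesis genes in 13 of 16 (0.12 ± 0.15, adjusted p = 0.0428, and adjusted p = 0.71 with an estimated correlation) and interferon response genes in 6 of 8 (0.35 ± 0.5, adjusted p = 0.0293, and adjusted p = 0.72 with an estimated correlation). PSMA7 stood at 222 ± 45.7 FPKM in DMSO and 297 ± 68.5 in DATS (SD, n = 3), and lanosterol synthase (LSS) at 12.9 ± 0.947 and 17.4 ± 2.5. The interferon-induced genes OAS1 and IFI6 stood at 1.72 ± 0.422 and 7.47 ± 3.28 FPKM in DMSO and at 4.41 ± 1.91 and 22.3 ± 15.4 in DATS. The proteasome list mean was -0.16, 0.13 and -0.14 in DMSO 1, 2 and 3 and 0.02, -0.06 and 0.21 in DATS 1, 2 and 3, so that DMSO 2 lay above DATS 1 and DATS 2. Of the 30 proteasome subunits, 0 had an unadjusted p under 0.05 in limma. In the interferon list DATS 1 (-0.16) lay below DMSO 3 (0.07). With the replicate number as a block the proteasome and cholesterol lists were no longer past the threshold (adjusted p = 0.0532 and 0.0909). Both calls were also lost under quantile scaling, tried on the lists after the data were seen (adjusted p = 0.352 and 0.136, with mean log2 differences of 0.04 and 0.08). The proteasome call was lost without DMSO 1, DMSO 3, DATS 1 or DATS 3 (adjusted p = 0.41, 0.194, 0.224 and 0.455) and the cholesterol call without DMSO 1, DMSO 2, DATS 1 or DATS 2 (adjusted p = 0.136, 0.126, 0.123 and 0.11). The interferon call was lost without DMSO 1, DMSO 2 or DATS 2 (adjusted p = 0.0682, 0.298 and 0.267) and after a correction for GC content and gene length (adjusted p = 0.0635, mean log2 difference 0.3 ± 0.46 after and 0.35 ± 0.5 before).

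**Figure D2:**
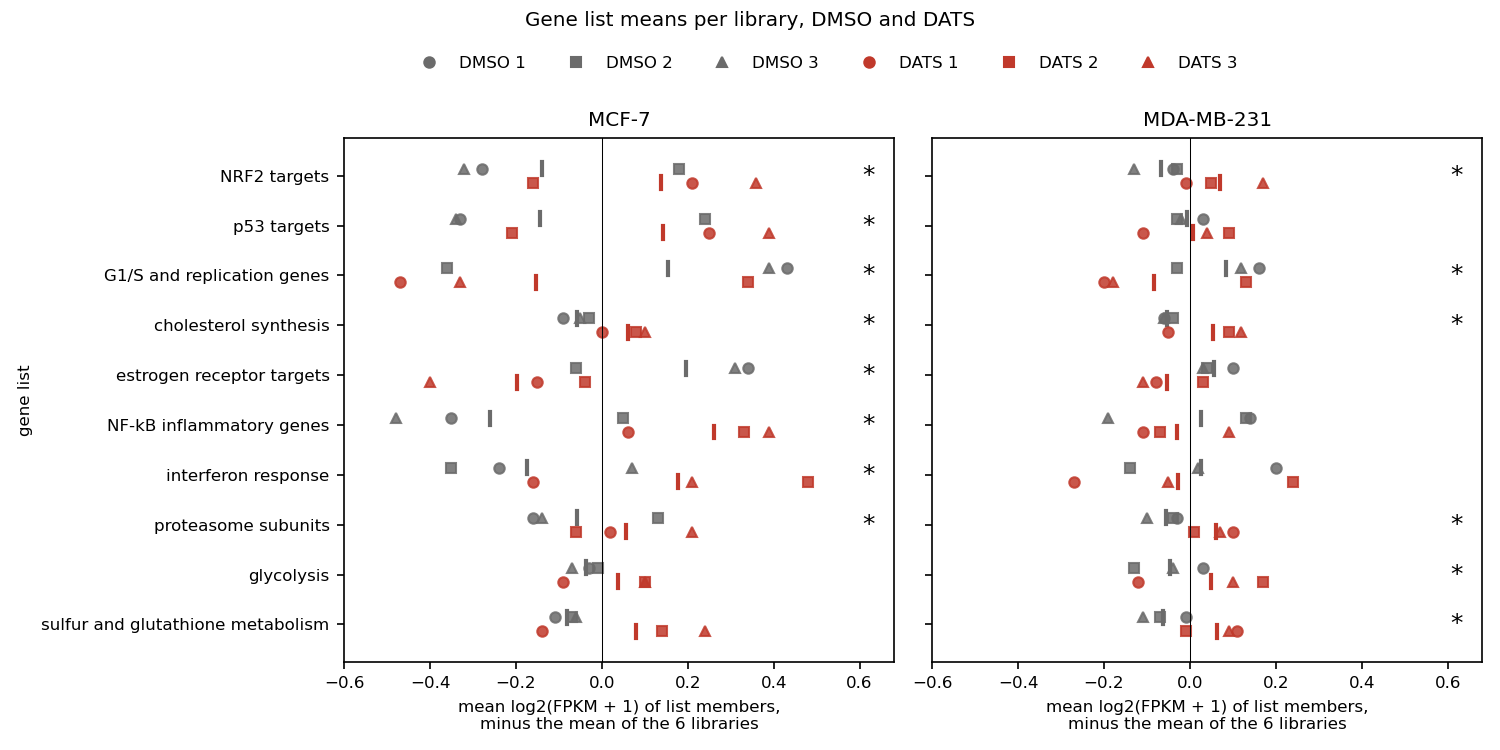
Mean log2(FPKM + 1) of the members of 10 gene lists in each library, relative to the mean of the 6 libraries of the line, for DMSO (grey) and DATS (red) libraries. Symbols give the replicate number, vertical bars the group means, and asterisks the lists past an adjusted p of 0.05 with the preset correlation. In MCF-7 the NF-kB means of all DATS libraries lie between 0.06 and 0.39 and those of the DMSO libraries between -0.48 and 0.05.

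**Figure D3:**
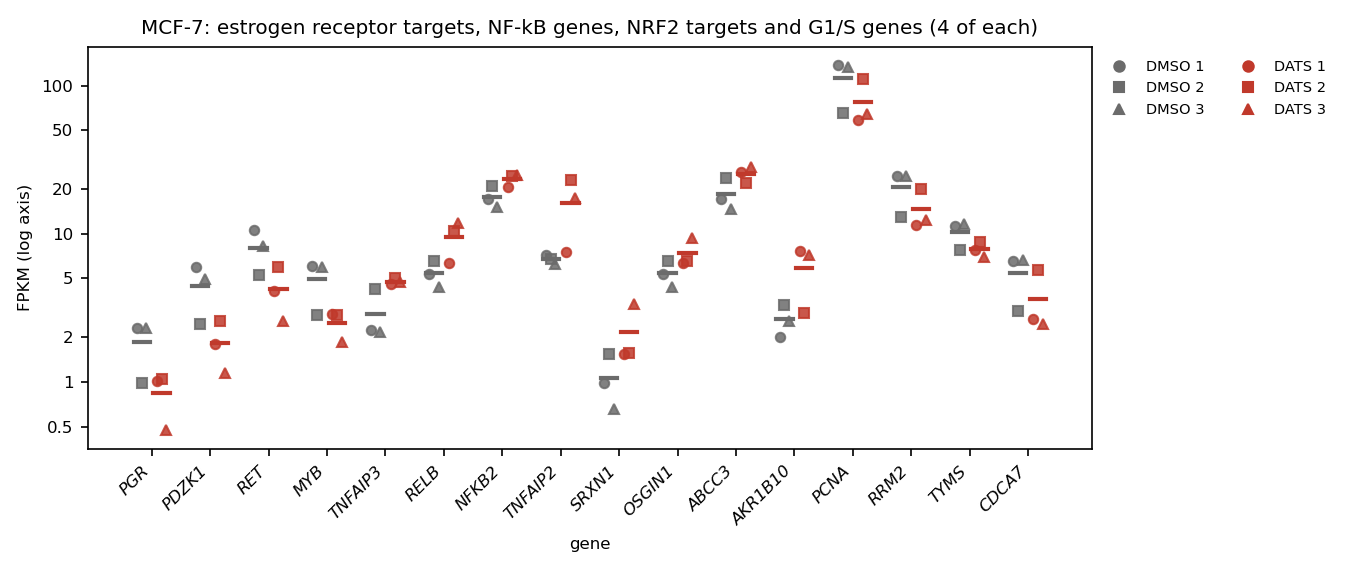
FPKM of 4 members each of the estrogen receptor target, NF-kB, NRF2 target and G1/S lists in the MCF-7 libraries, on a log axis. Points are libraries, with grey for DMSO and red for DATS, and horizontal bars are group means. TNFAIP2 has means of 6.72 and 16 FPKM and PCNA of 112 and 77.6 FPKM in DMSO and DATS.

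At the level of single genes in MCF-7, limma called 0 of 11871 genes at an adjusted p under 0.05, with 506 genes (4.3%) at an unadjusted p under 0.05. This limma share lies below the 0.05 that chance alone would give. On the recovered reads, edgeR's quasi-likelihood test also called 0 genes, with 571 at an unadjusted p under 0.05, and DESeq2 called 15 genes, 12 higher and 3 lower, with 639 at an unadjusted p under 0.05. The authors' deposited table listed 17 genes with an adjusted p under 0.05 in this line, 13 higher and 4 lower. Its smallest adjusted p belonged to TRIM31, a ubiquitin ligase gene on chromosome 6 (30102897 to 30113106, GRCh38), with a log2 fold change of 2.11 and an adjusted p of 1.24e-04 in the authors' deposited table. TRIM31 stood at 1.34 ± 0.611 FPKM in DMSO and 5.77 ± 2.78 in DATS (SD, n = 3), with a limma log2 difference of 1.48 ± 0.32 (SE) and an adjusted p of 0.841. The glutathione peroxidase gene GPX2 stood at 10.8 ± 3.45 and 33.6 ± 17.1 FPKM, the transcriptional repressor BHLHE41 at 1.14 ± 0.297 and 3.37 ± 1.15, and the calcium-binding protein gene S100P at 62.9 ± 12.2 and 145 ± 65.7. CEACAM5, a cell adhesion glycoprotein, stood at 13.9 ± 4 and 31.6 ± 9.75 FPKM. Lower means in DATS were found for IL20, with 4.19 ± 2.11 and 0.979 ± 0.398 FPKM, for the matrix Gla protein gene MGP, with 19.6 ± 6.25 and 9.45 ± 1.87, and for EVL, a regulator of actin, with 9.15 ± 1.14 and 5.2 ± 1.07. For all 17 genes every DATS library lay on one side of every DMSO library, a separation that chance gives to 10% of genes at this group size and that is more frequent among genes chosen for their difference. Of the 861 genes in the authors' deposited table for MCF-7 (each with an unadjusted p of 0.05 or less there), 641 were tested by limma. All 641 had the same direction, 368 had an unadjusted p under 0.05, and 0 passed the adjusted threshold. The shared direction is not independent evidence, since both tests used the same libraries and the genes were listed for their difference there. Differences between DATS and DMSO followed the GC content of the gene (Spearman rho = 0.5 across 11871 genes, which are not independent replicates) and, less closely, gene length (rho = -0.17).

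In MDA-MB-231 cells, proteasome subunits, enzymes of sulfur and glutathione metabolism, NRF2 targets, glycolytic and cholesterol synthesis genes were higher as groups after DATS, and G1/S genes were lower. Of 30 proteasome subunits, 22 had a higher mean in DATS, with a mean log2 difference of 0.11 ± 0.14 (SD over the members; camera adjusted p = 0.000658, and adjusted p = 0.71 with an estimated correlation). PSMB7 stood at 114 ± 8.34 FPKM in DMSO and 146 ± 12.4 in DATS (SD, n = 3), PSMA7 at 186 ± 12.9 and 247 ± 40, and PSMA5 at 36.7 ± 1.78 and 43.5 ± 0.283. In the sulfur and glutathione list 13 of 15 members had a higher mean (0.13 ± 0.14, camera adjusted p = 0.0109, and adjusted p = 0.72 with an estimated correlation). The persulfide dioxygenase gene ETHE1 stood at 7.1 ± 0.638 and 9.66 ± 0.918 FPKM, the sulfurtransferase gene TST at 6.67 ± 0.904 and 8.96 ± 1.96, and GSTM3 at 17.3 ± 0.927 and 21.1 ± 0.465. NRF2 targets were higher in 16 of 20 members (0.14 ± 0.18, camera adjusted p = 0.0177, and adjusted p = 0.71 with an estimated correlation). Among them the quinone reductase NQO1 stood at 42.4 ± 1.31 and 50.5 ± 1.16 FPKM, peroxiredoxin PRDX1 at 166 ± 7.81 and 207 ± 22.5, and heme oxygenase HMOX1 at 4.42 ± 0.406 and 5.73 ± 1.3. Glycolytic genes were higher in 15 of 18 members (0.1 ± 0.12, adjusted p = 0.0177, and adjusted p = 0.773 with an estimated correlation), with hexokinase HK1 at 39.1 ± 0.0599 and 44.6 ± 3.8 FPKM. Of these 18 members, 0 had an unadjusted p under 0.05 in limma, and 4 had all DATS libraries above all DMSO libraries. Cholesterol synthesis genes were higher in 13 of 17 (0.1 ± 0.14, adjusted p = 0.0185, and adjusted p = 0.71 with an estimated correlation), with INSIG1 at 8.78 ± 0.285 and 10.8 ± 0.803 FPKM and DHCR24 at 16.5 ± 1.5 and 20.7 ± 2.56. G1/S and replication genes were lower in 15 of 18 members (-0.17 ± 0.17, adjusted p = 0.00506, and adjusted p = 0.773 with an estimated correlation). Cyclin E2 (CCNE2) stood at 4.51 ± 0.171 and 3.4 ± 0.189 FPKM, the replicative helicase subunit MCM5 at 15.2 ± 0.624 and 12.3 ± 1.35, and TYMS at 33.2 ± 7.31 and 23.6 ± 4.53. The libraries numbered 2 stood apart from their groups in the G1/S list of this line too, with means, relative to all 6 MDA-MB-231 libraries, of -0.03 in DMSO 2 and 0.13 in DATS 2, against 0.16 and 0.12 in DMSO 1 and 3 and -0.2 and -0.18 in DATS 1 and 3. In the glycolysis list DATS 1 (-0.12) lay at the level of DMSO 2 (-0.13), and in the cholesterol list DATS 1 (-0.05) lay within the DMSO libraries (-0.06 to -0.04). In the sulfur and glutathione list DATS 2 (-0.01) lay at the level of DMSO 1 (-0.01).

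Each of these 6 MDA-MB-231 list calls was lost when certain libraries were left out. Without DATS 1 the adjusted p was 0.0806 for proteasome subunits, 0.216 for the sulfur and glutathione list and 0.216 for G1/S genes, and without DMSO 1 it was 0.0664 for G1/S genes and 0.0669 for cholesterol synthesis. It was 0.0594 for NRF2 targets without DATS 3, 0.194 and 0.258 for glycolysis without DMSO 2 or DATS 2, and 0.101 for cholesterol synthesis without DATS 2. Under quantile scaling the calls of glycolysis and NRF2 targets were lost (adjusted p = 0.4 and 0.0689). The mean log2 difference of NRF2 targets was then 0.11 and that of glycolysis 0.04, and that of proteasome subunits was 0.06, at an adjusted p that rounds to the threshold of 0.05. The sulfur and glutathione call was also lost after the correction for GC content and gene length (adjusted p = 0.172, mean log2 difference 0.06 ± 0.13 after and 0.13 ± 0.14 before). The MDA-MB-231 differences followed GC content (Spearman rho = 0.39 across 11420 genes) and gene length (rho = -0.35).

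Among single genes in MDA-MB-231, limma called 0 of 11420 at an adjusted p under 0.05, with 927 (8.1%) at an unadjusted p under 0.05. EdgeR called 0, with 1074 at an unadjusted p under 0.05, and DESeq2 called 18 genes, 16 higher and 2 lower, with 1033 at an unadjusted p under 0.05. DESeq2's filter on mean count left 9520 of the 11420 genes without an adjusted p, so its calls were adjusted over fewer genes. Without the library DATS 1, limma called 81 genes, 65 higher and 16 lower. The authors' deposited table listed 19 genes with an adjusted p under 0.05, 17 higher and 2 lower. Of these 19 genes of the authors' deposited table, 13 belonged to the ribosomal protein genes when FAU and the pseudogene RPL9P9 are counted. RPS27A, with 202 ± 3.34 FPKM in DMSO and 262 ± 8.21 in DATS (SD, n = 3), had a limma log2 difference of 0.38 ± 0.09 (SE, adjusted p = 0.534). RPL37A stood at 72 ± 1.78 and 95.1 ± 6.41 FPKM and RPS12 at 460 ± 6.63 and 621 ± 75.5. The respiratory chain subunit gene COX7C stood at 62.8 ± 4.14 and 90.3 ± 9.1 FPKM, and the glutathione transferase gene GSTO1 at 66.5 ± 6.19 and 89.7 ± 6.37. SRRM2, a splicing factor gene, stood at 36.2 ± 2.32 FPKM in DMSO and 27.8 ± 1.03 in DATS, and PRRC2C at 20.3 ± 1.79 and 15 ± 1.29. RPL9P9 stood at 121 ± 4.35 and 210 ± 59.9 FPKM, an uncertain value because reads of a pseudogene and its parent gene are hard to separate. In 17 of the 19 genes all DATS libraries lay on one side of all DMSO libraries, against 10% by chance for genes not chosen on their values. Of the 1152 genes in the authors' deposited table for this line, 1016 were tested by limma. All 1016 had the same direction, 723 had an unadjusted p under 0.05, and 0 passed the adjusted threshold. As in MCF-7, the same libraries went into both tests, so the shared direction is not independent evidence.

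**Figure D4:**
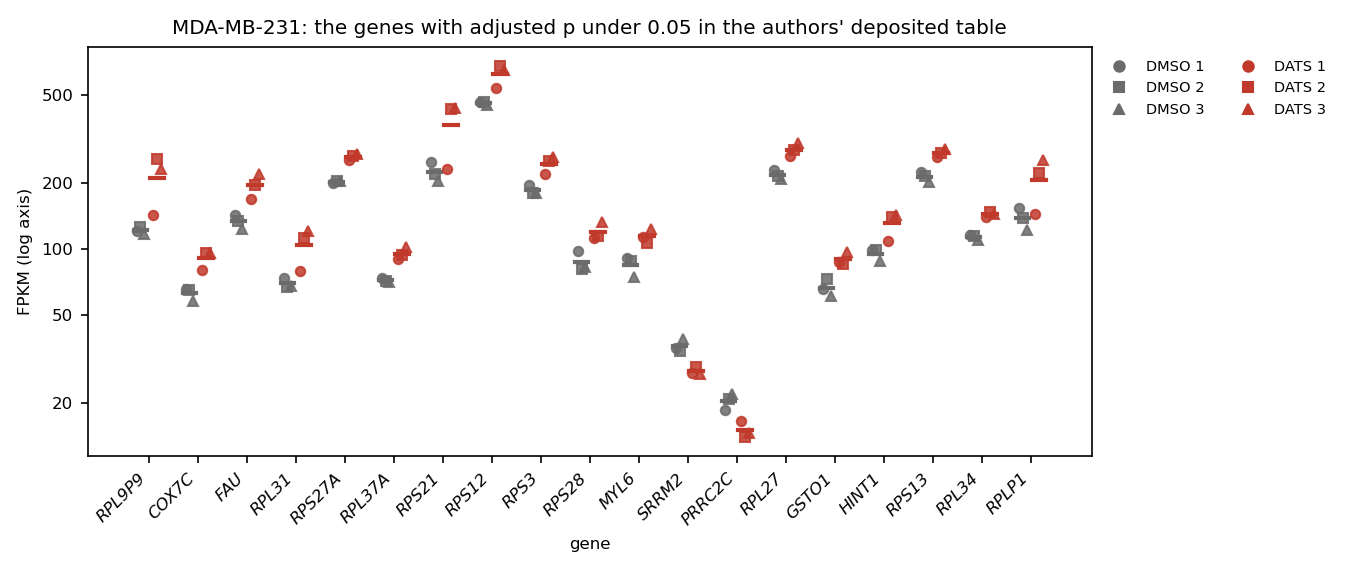
FPKM of the 19 genes with an adjusted p under 0.05 in the authors' deposited table for MDA-MB-231, in each library, on a log axis. Points are libraries, with grey for DMSO and red for DATS, and horizontal bars are group means. RPS21 and RPLP1 are the 2 genes whose DATS and DMSO libraries overlap.

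The responses of the 2 lines were then compared directly. The interaction test in limma called 1 of 9922 genes expressed in both lines, RPS3AP5, with 190 genes (1.9%) at an unadjusted p under 0.05. This share lies below the 0.05 that chance alone would give. EdgeR also called 1 gene, with 183 at an unadjusted p under 0.05, and DESeq2 called 2, with 201. RPS3AP5 is a processed pseudogene of the ribosomal protein gene RPS3A on chromosome 10 (84560443 to 84561263, GRCh38). Its log2 response in MDA-MB-231 exceeded that in MCF-7 by 1.81 ± 0.22 (SE, limma adjusted p = 0.0197). The values rest on 5 reads in each MDA-MB-231 DMSO library and 23 to 28 reads in each MDA-MB-231 DATS library, and on 35 to 49 reads in MCF-7 DMSO and 10 to 23 reads in MCF-7 DATS. The parent gene RPS3A had 12542 to 17986 reads, so the pseudogene's level is uncertain where reads are shared. The call was lost without MCF-7 DMSO 2, DMSO 3 or DATS 1 (adjusted p = 0.0544, 0.0653 and 0.0805), without MDA-MB-231 DMSO 1, DMSO 2 or DMSO 3 (0.0887, 0.0916 and 0.0828), and without any single MDA-MB-231 DATS library, where the gene fell below the expression filter. It was also lost with the replicate number as a block within each line (0.0641), and kept with treatment and number as a block across the lines, tried after the data were seen (0.0376). The second DESeq2 call was EVL, at an adjusted p of 0.0427 in DESeq2 and of 1 in limma. Among the gene lists, the difference between the lines had a camera adjusted p of 4.18e-09 for the NF-kB genes (mean log2 difference -0.57, MDA-MB-231 minus MCF-7, and adjusted p = 0.209 with an estimated correlation) and of 0.0161 for the p53 targets (-0.25, and adjusted p = 0.873 with an estimated correlation), in a test added after the data were seen. The p53 list was no longer past the threshold without MCF-7 DMSO 1, DMSO 3, DATS 1 or DATS 3 (adjusted p = 0.217, 0.134, 0.271 and 0.313) or MDA-MB-231 DATS 1 (0.106). The other 23 lists did not pass, with estrogen receptor targets at 0.114, interferon response at 0.153, G1/S genes at 0.158, NRF2 targets at 0.41, the sulfur and glutathione list at 0.593, glycolysis at 0.577, and the proteasome and cholesterol lists at 0.838 each. With treatment and number as a block across the lines, the NF-kB and p53 lists stayed past the threshold at the preset correlation (camera adjusted p = 1.97e-09 and 0.0177). Estrogen receptor targets and interferon response then passed (0.0473 for both). An estimated correlation was not tried with this block, and without the block it gave 0.696 and 0.723 for these 2 lists.

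The single genes called in both lines numbered 0 in DESeq2, and 0 in limma and edgeR, which called none in either line. At an unadjusted p under 0.05, 35 genes were higher after DATS in both lines and 10 were lower in both, where 9.2 and 3.8 would be expected if genes and lines were independent. Across the 9922 genes the log2 differences of the lines had a Spearman rho of 0.53 and a Pearson r of 0.5, and 70.4% of genes had the same sign. After the correction for GC content and gene length, rho was 0.4 and 64.7% had the same sign. The lines were not independent, since libraries of the same treatment and number moved alike in both. The deviations from the group mean correlated at 0.13, 0.15 and 0.2 between the lines for DMSO 1, 2 and 3 and at 0.53, 0.34 and 0.49 for DATS 1, 2 and 3, and each library correlated best with its own number. When both lines were divided by the same split of the 6 libraries, 4 of 10 splits gave at least 45 genes in the same direction in both lines and 3 of 10 a rho of at least 0.53, the labelled split included, with up to 592 genes and a rho of up to 0.72 in another split. These splits were examined after the data were seen. The overlap therefore does not separate an effect of DATS from this shared structure.

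The remaining gene lists did not pass the list test in either line, apart from the settings given below. Camera gave an adjusted p of 0.57 in MCF-7 and 0.327 in MDA-MB-231 for the integrated stress response, 0.749 and 0.513 for the unfolded protein response, 0.749 and 0.794 for the heat shock response, and 0.836 and 0.411 for metallothioneins, which camera ranked lower in MCF-7 although their mean log2 difference was 0.02 and their median 0.09. G2/M genes had adjusted p values of 0.575 and 0.0922, with 13 of 18 members lower in MDA-MB-231, including MKI67 at 35.9 ± 5.6 FPKM in DMSO and 27.5 ± 2.81 in DATS (SD, n = 3). For the BCL2 and IAP families the adjusted p was 0.254 and 0.453, for fatty acid synthesis 0.271 and 0.298, for mesenchymal genes 0.165 and 0.528, and for epithelial luminal genes 0.695 and 0.255. Keratin 18 (KRT18), the luminal gene with the smallest p in MCF-7, stood at 1200 ± 24.2 FPKM in DMSO and 908 ± 15.1 in DATS (limma adjusted p = 0.841). FOXO targets gave 0.812 and 0.756, stem-like cell markers 0.443 and 0.661, immediate-early AP-1 genes 0.216 and 0.411, hypoxia genes 0.812 and 0.0922, tubulins 0.299 and 0.453, and mitochondrially encoded genes 0.101 and 0.309. The lists past the threshold in MCF-7 alone had adjusted p values in MDA-MB-231 of 0.136 (estrogen receptor targets), 0.575 (NF-kB genes), 0.794 (p53 targets) and 0.54 (interferon response). Without MDA-MB-231 DMSO 3, the estrogen receptor target and NF-kB lists passed as lower after DATS in that line (adjusted p = 0.0295 and 0.00381). Glycolysis and the sulfur and glutathione list had adjusted p values of 0.29 and 0.191 in MCF-7. In MDA-MB-231 the G2/M list passed without DMSO 2 or DATS 1 (adjusted p = 0.0029 and 0.0489) and with the replicate number as a block (0.041) or under TPM or quantile scaling (0.0491 and 0.00668), immediate-early genes without DMSO 1 (0.0307), hypoxia genes without DATS 3 (0.0346) and mitochondrially encoded genes without DATS 1 (1.8e-05). In MCF-7 mitochondrially encoded genes passed without DATS 3 (0.0131) and under TPM scaling (0.0358). After the correction for GC content and gene length, tubulins passed in MCF-7 (0.0259), and tubulins, hypoxia genes, G2/M genes and estrogen receptor targets in MDA-MB-231 (0.0118, 0.0118, 0.0428 and 0.0081). Outside the NF-kB list in MCF-7, the only list member that passed when adjusted over the list alone was the mitochondrial chaperonin gene HSPE1 of the heat shock list in MDA-MB-231, at 27.8 ± 1.92 FPKM in DMSO and 45.1 ± 9.5 in DATS (limma adjusted p = 0.0299 over the list and 0.534 over all genes).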

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

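The gene lists were tested on the difference between the lines only after the data had been seen, while the test of single genes was planned. The NF-kB list stood out because its response to DATS differed between the lines, with a mean log2 difference of -0.57 for MDA-MB-231 minus MCF-7 over 8 members (camera adjusted p = 4.18e-09, and adjusted p = 0.209 with an estimated correlation). These 8, of 18 in the list, are the members that passed the expression filter in both lines. All 8 members had the lower value in MDA-MB-231. TNFAIP2 had a log2 difference of 1.02 in MCF-7 and -0.09 in MDA-MB-231, BIRC3 of 0.32 and -0.37, and RELB of 0.69 and 0.13. The adjusted p of the list without any single library ranged from 8.44e-11 to 2.17e-06, and after the correction for GC content and gene length it was 9.66e-11. All of these values used the preset correlation, so they do not bear on the loss of the call with an estimated correlation.

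The p53 target list also differed between the lines, with a mean log2 difference of -0.25 for MDA-MB-231 minus MCF-7 and 14 of 15 members lower (camera adjusted p = 0.0161, and adjusted p = 0.873 with an estimated correlation). BBC3 had a log2 difference of 0.59 in MCF-7 and 0.11 in MDA-MB-231, and TP53INP1 of 0.39 and 0.03. The call was lost without MCF-7 DMSO 1, MCF-7 DMSO 3, MCF-7 DATS 1, MCF-7 DATS 3 or MDA-MB-231 DATS 1 (adjusted p = 0.217, 0.134, 0.271, 0.313 and 0.106), and was kept after the correction for GC content and gene length (0.00513), all at the preset correlation.

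The pseudogene RPS3AP5 was the single gene whose response differed between the lines in limma, with an adjusted p of 0.0197, a log2 difference of -0.8 in MCF-7 and of 1.01 in MDA-MB-231. The 3 MDA-MB-231 DMSO libraries held 5 reads each. Its parent RPS3A had log2 differences of -0.1 ± 0.12 and 0.17 ± 0.11 (SE) in the same order. Leaving out MCF-7 DMSO 2, DMSO 3 or DATS 1 ended the RPS3AP5 call (adjusted p = 0.0544, 0.0653 and 0.0805), as did leaving out MDA-MB-231 DMSO 1, DMSO 2 or DMSO 3 (0.0887, 0.0916 and 0.0828), and without any single MDA-MB-231 DATS library the gene fell below the expression filter. With the replicate number as a block within each line the call was lost too (0.0641), and with treatment and number as a block across the lines, tried after the data were seen, it was kept (0.0376). Of 100 splits of the treatment labels within the lines, drawn from 200, 14 called at least 1 gene, the real one included, so chance is not excluded for this count. These splits divided each line independently, which leaves aside that libraries of the same treatment and number moved alike in both. The highest other split called 1656 genes, which points to a structure of the samples that the treatment labels do not follow.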

How the results depend on the processing

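The DATS gene counts did not move with pseudocount, expression filter, scaling, eBayes setting, edgeR or GC and length correction. In MCF-7 the count of 0 became 15 with DESeq2 and 2 with all 12 libraries in one fit (AC025166.1 and AL691482.2, named after their values were seen, as are the genes below), and stayed at 0 without any single library. In MDA-MB-231 it became 18 with DESeq2 and 4 without both libraries numbered 2 (HIST2H2BE, HIST1H2BD, NR1D1 and MMP1; an alternative chosen after the data were seen, as were the GC and length correction and protein-coding genes alone), and ranged from 0 to 81 when single libraries were left out, with 81 reached without DATS 1. The count of 1 gene whose response differed between the lines became 2 with DESeq2 and 0 without a filter, where RPS3AP5 had an adjusted p of 0.097 among 24369 genes, or with a filter at 5 FPKM, which it does not pass, and ranged from 0 to 1 without single libraries. The count of 14 list calls became 0 with an estimated correlation and ranged from 9 (without MCF-7 DMSO 1 or MCF-7 DATS 1) to 16 without single libraries. After GC and length correction there were 17 list calls, with 12 of the 14 kept and 5 gained (tubulins in both lines, and G2/M genes, estrogen receptor targets and hypoxia genes in MDA-MB-231). TPM and quantile scaling, tried on the lists after the data were seen, gave 16 and 11 list calls. TPM kept all 14 and gained mitochondrially encoded genes in MCF-7 and G2/M genes in MDA-MB-231. Quantile scaling kept 10 (proteasome subunits in MDA-MB-231 at an adjusted p that rounds to 0.05), gained G2/M genes in MDA-MB-231 and lost proteasome subunits and cholesterol synthesis in MCF-7 and NRF2 targets and glycolysis in MDA-MB-231. Without both libraries numbered 2 there were 15, with 10 kept, cholesterol synthesis in both lines, interferon response in MCF-7 and glycolysis in MDA-MB-231 lost, and stem-like markers in MCF-7 (adjusted p = 0.0327) and G2/M genes, fatty acid synthesis, interferon response and tubulins in MDA-MB-231 (0.00149, 0.0467, 0.00722 and 0.0467) gained. The baseline count of 9619 was 9569 to 12825 under a pseudocount of 0.1, median-of-ratios scaling, no filter and the replicate block and 7783 to 8550 without single libraries, where the filter of 3 libraries removes genes expressed in the smaller group alone. The cause of the other changes was not tested. The count of calls shared by the lines was not informative in limma, which called 0 genes in each line at a 2-fold minimum, a pseudocount of 0.1 and median-of-ratios scaling (506 and 927 genes had an unadjusted p under 0.05 in the test as reported, edgeR called 0 and DESeq2 called 15 and 18). Of the alternative values of named genes, 2093 kept their side of the threshold and direction, 10 moved past it, 7 fell below it and 3 changed sign while past it in neither, and of those of lists 583, 22, 51 and 44 did. Depth limits low genes, as RPS3AP5 with 5 reads per MDA-MB-231 DMSO library shows.

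Replicate numbers did not pair DMSO with DATS libraries within a line, since the deviations of same-numbered DMSO and DATS libraries correlated negatively in all 6 pairs (-0.22, -0.44 and -0.4 in MCF-7, -0.34, -0.42 and -0.3 in MDA-MB-231), and no library correlated best with its own number there. Across the lines, libraries of the same treatment and number correlated positively, at 0.13 to 0.53. With treatment and number as a block across the lines, chosen after the data were seen, the count of genes whose response differed stayed at 1. With the replicate number as a block, limma called 0 genes in MCF-7, 1 gene in MDA-MB-231 (MIR5587), 0 genes for the difference between the lines, 9722 genes between the lines in DMSO, and camera called 13 lists, with cholesterol synthesis and proteasome subunits lost in MCF-7 and G2/M genes gained in MDA-MB-231.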

Other observations

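The tests of GC content on splits and list calls, of an exchange of libraries, of a difference in proliferation, the splits of the DATS gene counts and the ribosomal protein class were chosen after the results they measure were seen. The ribosomal protein genes as a class, chosen because they filled the authors' deposited table for MDA-MB-231, were higher in 76 of 83 protein-coding members after DATS in that line, with a median log2 difference of 0.21 and an SD of 0.19 over members. Camera gave an unadjusted p = 2.89e-21 with the preset correlation and an unadjusted p = 0.0389 with an estimated correlation, which is not independent evidence because the class was picked from these data. The class mean, relative to all 6 MDA-MB-231 libraries, was -0.03, -0.15 and -0.17 in the DMSO libraries and 0.1, 0.08 and 0.17 in the DATS libraries. In MCF-7, 67 of 83 members were higher with a median of 0.17, at a camera unadjusted p = 3.25e-06 with the preset and an unadjusted p = 0.423 with an estimated correlation. The MCF-7 class mean was -0.18, 0.07 and -0.15 in DMSO 1, 2 and 3 and -0.14, 0.07 and 0.33 in DATS 1, 2 and 3. DATS 1 thus lay with DMSO 1 and DMSO 3, DATS 2 lay at the level of DMSO 2, and only DATS 3 lay above all DMSO libraries. The medians were 0.18 in MDA-MB-231 and 0.14 in MCF-7 after the GC and length correction, 0.22 and 0.17 under median-of-ratios, 0.19 and 0.15 under TPM, and 0.12 and 0.07 under quantile scaling.

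At baseline, where 9619 of 12628 genes were called by limma and no list test was run, the called members of some lists lay mostly in one direction. Of 15 NF-kB genes tested, 14 were higher and 1 lower in MDA-MB-231 DMSO cells (median log2 difference 2.61), and of 6 metallothionein list genes 5 were higher and 0 lower (median 2.26). Of 18 G2/M genes 12 were higher and 0 lower (median 1.06). Of 17 estrogen receptor targets 13 were lower and 1 higher in MDA-MB-231 (median -2.4), and of 17 cholesterol synthesis genes 13 were lower and 2 higher (median -0.85). Targets of p53, which is wild-type in MCF-7 and mutant in MDA-MB-231, were lower in 11 and higher in 4 of 17 (median -1.09).

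In MCF-7 the labelled split of the 6 libraries called 0 genes in limma (506 at an unadjusted p under 0.05, 0 in edgeR and 15 in DESeq2), while the split of DMSO 1, DMSO 3 and DATS 2 from DMSO 2, DATS 1 and DATS 3 called 333, which points to a structure of the samples other than the treatment labels. Of the 9 other splits 8 called 0 genes, and since the labels call 0, all 10 of 10 splits reach their count by construction, while 10 splits are too few for a share under 0.05. The correction argues against GC and length bias as the whole source, since after it the split called 1349 genes. An exchange of the 2 libraries numbered 2 stays open as a hypothesis. NRF2 targets, which respond to thiol-reactive compounds, were higher in DMSO 2 than in DATS 2 by 0.33 ± 0.07 on the log2 scale (SE over 22 members, 20 of them higher). Their means separated along that split. DMSO 2 minus DATS 2 also ran against the labels for p53 targets (0.45 ± 0.09), G1/S genes (-0.69 ± 0.07) and proteasome subunits (0.2 ± 0.03). It ran as the labels have it for interferon response, at -0.83 ± 0.32 (SE over 8 members). NF-kB genes (-0.28 ± 0.24, 8 members), cholesterol synthesis (-0.11 ± 0.07) and sulfur and glutathione metabolism (-0.21 ± 0.12, 13 members) did too, but within 2 SE of 0. Estrogen receptor targets gave -0.02 ± 0.09. The SEs in this paragraph are taken over list members, which are not independent, and do not measure the spread between libraries. The 17 genes past 0.05 in the authors' deposited table also kept both libraries with their labelled groups, but they were chosen on those labels. A difference in proliferation between the dishes, a biological hypothesis, cannot be told apart either, since the G1/S list was higher on the side of DMSO 1 by 0.77 ± 0.06 (SE over 18 members) and the G2/M list had a log2 difference of -0.22 ± 0.15, against the direction that proliferation would give, with 5 of 18 members higher on the side of DMSO 1 and list means that separated along the split in that opposite direction, but within 2 SE of 0.

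In MDA-MB-231 the same combination of numbers called 12 genes in limma against 0 for the labels (927 at an unadjusted p under 0.05, 0 in edgeR and 18 in DESeq2), and 122 after the GC and length correction, which argues against that bias as the whole source. Of the 9 other splits 8 called 0, all 10 of 10 splits reach the labelled count of 0 by construction, and their number is too small for a share under 0.05. By the NRF2 list, an exchange of the libraries numbered 2 in this line cannot be told apart from their labels being right. DMSO 2 minus DATS 2 was -0.09 ± 0.07 there (SE over 20 members), within 2 SE of 0. Glycolysis (-0.31 ± 0.05) and cholesterol synthesis (-0.13 ± 0.03) ran as the labels have it, and G1/S genes (-0.16 ± 0.06) ran against them. Proteasome subunits (-0.05 ± 0.03) and the sulfur and glutathione list (-0.06 ± 0.07) ran as labelled, within 2 SE of 0. The SEs in this paragraph are taken over list members and do not measure the spread between libraries, so they cannot decide the question. A difference in proliferation between the dishes stays open as a biological hypothesis, since the G1/S and G2/M list means both separated along this split, higher on the side of DMSO 1 by 0.27 ± 0.05 and 0.21 ± 0.07 (SE over 18 members each).

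Differences between DATS and DMSO followed GC content in both lines, with positive trends in the DATS 2 and DATS 3 libraries (Spearman rho against GC content 0.47 and 0.53 in MCF-7, 0.19 and 0.63 in MDA-MB-231) and negative ones in DATS 1 (-0.39 and -0.36). GC and length bias as the whole source of the list calls is argued against by the correction, after which 85.7% of the 14 calls held in the same direction, the interferon list in MCF-7 and the sulfur and glutathione list in MDA-MB-231 being lost. For the 19 MDA-MB-231 genes past 0.05 in the authors' deposited table, a test fixed before its result was seen gave a median log2 difference in their own direction of 0.39 after the correction against 0.43 before, or 91.1%, with all 19 on the same side. These genes were chosen for their difference between the same libraries, so a smooth trend over all genes could hardly remove it. Gene length was the union of exons (6841 bp for RPL37A), not that of the expressed transcript. The test therefore cannot exclude a bias that this trend does not describe. Whether the remaining differences come from DATS stays open, since the labelled split does not stand out for single genes.

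For the list calls, 9 of 100 joint splits of the 2 lines called at least 14 lists, the real one included, with up to 17 in another split, so chance is not excluded for their number. The median over the 100 splits was 9 lists, so splits other than the labels often passed the list test at the preset correlation. The lines were split independently, which leaves aside that libraries of the same treatment and number moved alike in both. For the baseline, 1 of 10 splits of the DMSO libraries, the real one, reached 9619 genes, and the highest other called 0, but 10 splits are too few for a share under 0.05.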
